A study of Homo sapiens with 6 samples.

How the data were processed

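RNA from clonal MiaPaCa2 cells was measured in 6 libraries, 3 from ZEB1-deleted clones and 3 from wild-type clones, each made from 2000 lysed cells grown in medium with 10% serum. Per the labels' protocols, the clones were isolated by sorting GFP-positive cells after electroporation of a Cas9-GFP plasmid, and the cDNA was made with SMART-Seq2, tagmented, amplified and sequenced on an Illumina HiSeq 2000. SMART-Seq2 does not record the strand, so reads from a gene and an overlapping antisense gene cannot be separated, and its amplified fragments carry no molecular identifiers. Groups and replicate numbers came from the sample titles. Replicates were separate clones per the series design, while nothing in the labels gives their culture days or library batches.

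Count, TPM and result tables were used. The authors deposited raw counts per gene symbol for 26334 symbols, a table of TPM values for a subset of these genes, scaled to the same total in each library, and a table of edgeR results for the same subset with a log2 fold change, average log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value per gene, per the file headers. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq 0.6.1 and edgeR 3.2.2 were used with builds hg19 and GRCh37, without their settings. The filter that led to this subset and the gene lengths behind the TPM values are not given in the sources used here. The deposited log2 fold change is ZEB1-KO over WT, as checked against the deposited counts: its correlation across genes with the fit made here was 1.00, over genes that are not independent replicates.

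The deposited counts, which total 18909305 to 42876693 per library, were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at its default minimum count of 10 and total of 15, leaving 13659 genes. Libraries were scaled with TMM factors, and a model with the group alone was fitted with glmQLFit and tested with glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 4 residual and 4.35 prior degrees of freedom. CPM values use the TMM-scaled library sizes, and log2 CPM used for correlations and principal components has a prior count of 2. The SE of a log2 fold change was derived from the F statistic. Counts of pairs of libraries differed by far more than sampling noise, with a chi-square per gene of at least 127, so that no library was a copy of another.

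The genes named were fixed before the data were examined: ZEB1, CDH1, EPCAM, ESRP1, GRHL2, OVOL2, VIM, CDH2, FN1, SNAI2 and ZEB2 whatever their result, then up to 12 with the largest rise and 12 with the largest fall among genes past the threshold with no overlap between groups and a mean of at least 5 CPM in the higher group, then up to 4 members past the threshold from each list. This gave 11 rises and 8 falls, and 5 further calls and list members named beyond these were chosen after their values were seen. The tests, their alternatives and 22 gene lists were also fixed before the data were examined: epithelial junctions and polarity, epithelial regulators, epithelial surface and trafficking, keratins, mesenchymal and extracellular matrix, other transcription factors of the transition, TGF-beta response, YAP and TEAD targets, neuroendocrine and neuronal, interferon response, hypoxia and glycolysis, cell cycle, cholesterol synthesis, stress response, p53 targets, markers of blood, endothelial and fibroblast cells, markers of pancreatic acinar and islet cells, cancer-testis genes, protocadherins, HOX genes, ribosomal proteins and histones. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 21 lists, and again with an estimated correlation and with fry.

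The counts of calls, the calls per list and the fold changes of the named genes were recomputed with other scaling factors (RLE, upper quartile, library size alone), without a filter, with a filter of 1 CPM in 3 libraries, with DESeq2 1.42.0, with edgeR's exact test, with limma-voom, with limma on log2 of the deposited TPM plus 1 or plus 0.1 (genes of mean TPM of at least 1, or no filter), with the replicate number as a block, and without each library in turn. The likelihood ratio test, robust estimation and an adjusted p below 0.1 were added after seeing the data. The list tests were repeated with an estimated correlation, with fry, with the block and without each library. DESeq2 was run on all deposited genes with its own filter, which left 13135 genes with an adjusted p. Its calls thus differ in the genes covered as well as in the test, and 575 of the 13659 genes had no adjusted p from it.

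The tests were tried on simulated data, in 5 simulations of this comparison over the 13659 genes with 200 genes changed. The quasi-likelihood test recovered 3.88% of 2-fold, 55.2% of 4-fold and 81.8% of 8-fold changes with 9.83% false calls among its calls, and the likelihood ratio test recovered 14.0%, 74.0% and 91.5% with 23.2% false calls. DESeq2 recovered 17.9%, 76.7% and 89.1% with 25.7% false calls. No call had the wrong sign. Mean calls per simulation were 103.8 for the quasi-likelihood test, 155.4 for the likelihood ratio test and 164.4 for DESeq2. Counts were drawn from a negative binomial model with the fitted dispersions, so these rates need not hold for the data.

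The annotation used here is of GRCh38, so that it served only for gene names, the order of genes along chromosomes (RefSeq, GRCh38.p14) and transcript length and GC content (GENCODE, GRCh38), and no coordinates are given. Of the 13659 genes tested, 13341 matched its current or older symbols. Gene order was used for 9068 genes with an average log2 CPM above 2. Plots were drawn with matplotlib 3.10.9.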

Results

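Messenger RNA was profiled in clones of MiaPaCa2, a human cell line derived from a pancreatic ductal adenocarcinoma, a tumour type in which cells can shift from an epithelial to a mesenchymal state. The clones, isolated by cell sorting, fell into 2 groups: 3 clones in which ZEB1, a zinc-finger repressor of epithelial genes, had been deleted with CRISPR-Cas9 (ZEB1-KO), and 3 clones that kept the wild-type gene (WT). Each library was made from 2000 lysed cells with SMART-Seq2, which copies polyadenylated RNA from an oligo(dT) primer and amplifies the cDNA. The total count was 42876693, 36290148 and 26242238 in WT replicates 1, 2 and 3 and 18909305, 36798770 and 32149376 in ZEB1-KO replicates 1, 2 and 3, and between 16552 and 17530 gene symbols had at least 1 count. A floor of 3 counts corresponded to between 0.0687 and 0.150 CPM (counts-per-million of the TMM-scaled library size). Floors of this kind cover counting error only, since amplified reads are not independent molecules. Genes are named by the symbols of the deposited tables.

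The targeted gene was examined first. ZEB1 had 1486, 1011 and 830 counts in WT replicates 1, 2 and 3, against 67, 140 and 369 counts in ZEB1-KO replicates 1, 2 and 3. Its mean level was 32.9 CPM ± 1.54 (SD, n = 3) in WT clones and 6.09 CPM ± 4.67 (SD, n = 3) in ZEB1-KO clones, and each ZEB1-KO value lay below each WT value. The log2 fold change was -2.43 with an SE of 0.49, but the adjusted p of 0.0930 from edgeR's quasi-likelihood test did not pass 0.05. Without ZEB1-KO replicate 3 the log2 fold change was -3.27 with an adjusted p of 0.0137, within a range of 3.3e-05 to 0.278 over all alternatives. In the authors' deposited table, from edgeR's likelihood ratio test, ZEB1 was lower by a log2 fold change of -2.44 with an adjusted p of 0.000391. ZEB1 transcript was thus still counted in every ZEB1-KO library, and the position of the deletion relative to the counted exons is not given in the sources used here.

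The comparison of the 3 ZEB1-KO with the 3 WT clones addressed which genes differ in level when ZEB1 is deleted, in a series concerned with the control of the epithelial-mesenchymal transition. The largest fold rise among the named genes belonged to SYNE4, which encodes nesprin-4, an epithelial protein of the outer nuclear membrane, at 0.189 CPM ± 0.0586 in WT and 18.4 CPM ± 6.30 in ZEB1-KO clones (SD, n = 3 each), a 93.1-fold difference. F11R, which encodes the tight-junction protein JAM-A, rose 23.1-fold, from 3.62 CPM ± 1.76 to 84.0 CPM ± 9.83 (SD, n = 3 each). TNS4, a tensin of focal adhesions, rose 24.9-fold, and ITGA2, the collagen-binding integrin alpha-2 chain, rose 24.0-fold.

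Among the 13659 genes tested with edgeR's quasi-likelihood test, 16 were higher and 8 were lower in ZEB1-KO clones at an adjusted p below 0.05. SYNE4 had a log2 fold change of 6.54 with an SE of 0.44 and an adjusted p of 0.00179. F11R had a log2 fold change of 4.53 with an SE of 0.38 and an adjusted p of 0.00765. TSPAN13, a tetraspanin of the cell surface, rose by 3.85 on the log2 scale (adjusted p = 0.00990), from 0.648 CPM ± 0.194 to 9.41 CPM ± 1.41 (SD, n = 3 each). RHOBTB3 rose by 3.63, though ZEB1-KO replicate 2 had 4371 counts against 740 and 1193 in the other clones of its group. The enzymes NMRK1, which phosphorylates nicotinamide riboside, and DHDH, a dihydrodiol dehydrogenase, rose by 3.26 and 2.76. PTGFRN, a tetraspanin-associated membrane protein, rose by 2.96, the glutaredoxin gene GLRX by 2.25, and TRAFD1, a regulator of innate immune signalling, by 2.02. Adjusted p-values for the rises of TNS4, ITGA2, RHOBTB3, NMRK1, PTGFRN, DHDH, GLRX and TRAFD1 lay between 0.0211 and 0.0475. Of these 11 named rises, 3 stayed past 0.05 without WT replicate 1, 3 without WT replicate 2, 2 without WT replicate 3 and 3 without ZEB1-KO replicate 1, against 6 and 7 without ZEB1-KO replicates 2 and 3, with adjusted p-values up to 0.193 (RHOBTB3) and each log2 fold change at 1.97 or above. Another 5 genes rose from low levels in the WT clones and were named after their values were seen: RNF43 and USP43, with 0 to 2 counts in each WT library and 25 to 38 counts in each ZEB1-KO library, and LCN2, EFNA3 and NIPAL1, with log2 fold changes of 4.45, 4.01 and 3.42. LCN2 encodes the secreted protein lipocalin-2, and RNF43 a ubiquitin ligase that removes Wnt receptors from the cell surface.

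The falls were led by COL1A2, the only collagen gene among the calls. COL1A2, which encodes the alpha-2 chain of type I collagen, dropped from 270.1 CPM ± 154 to 1.66 CPM ± 1.47 (SD, n = 3 each), a 169-fold difference with a log2 fold change of -7.40, an SE of 0.89 and an adjusted p of 0.0271. RNF182, a brain-enriched ubiquitin ligase gene, had 1319, 1196 and 1163 counts in the WT libraries and 7, 26 and 10 counts in the ZEB1-KO libraries, and its log2 fold change of -6.40 had an SE of 0.40 and an adjusted p of 0.00179. SATB1, a chromatin organizer, fell 80.3-fold, from 11.3 CPM ± 3.78 to 0.147 CPM ± 0.107 (SD, n = 3 each), with an adjusted p of 0.0182. AHNAK2, which encodes a large scaffold protein, had a log2 fold change of -3.55 with an adjusted p of 0.00863, and MVP, the major vault protein, one of -2.79 with an adjusted p of 0.0182. ATP2B4, a plasma-membrane calcium pump, fell by 2.28 on the log2 scale, and RSF1, a chromatin remodelling subunit, by 1.34. The histone H4 gene HIST1H4C fell by 2.24, from 1005 CPM ± 329 to 212.8 CPM ± 55.6 (SD, n = 3 each). This gene is similar in sequence to other H4 genes, so that its count may be uncertain. The oligo(dT) primer targets polyadenylated RNA, so histone RNA without a poly(A) tail may be missed. Of the 8 named falls, 6 stayed past 0.05 without WT replicate 1, 2 without WT replicate 2, 2 without WT replicate 3, 2 without ZEB1-KO replicate 1, and 4 without ZEB1-KO replicate 2 or 3, with adjusted p-values up to 0.191 (RSF1).

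The number of calls depended on the libraries and on the test. It was 13 without WT replicate 1, 6 without WT replicate 2, 5 without WT replicate 3, 6 without ZEB1-KO replicate 1, 16 without ZEB1-KO replicate 2 and 25 without ZEB1-KO replicate 3 (11 of them shared), against 24 from all libraries and 617 from edgeR's likelihood ratio test, and of the named genes only RNF182, AHNAK2, SYNE4 and F11R stayed past 0.05 in every one of these fits. An exact permutation test of a single gene could not go below p = 0.1 with 3 against 3 clones.

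**Figure D1:**
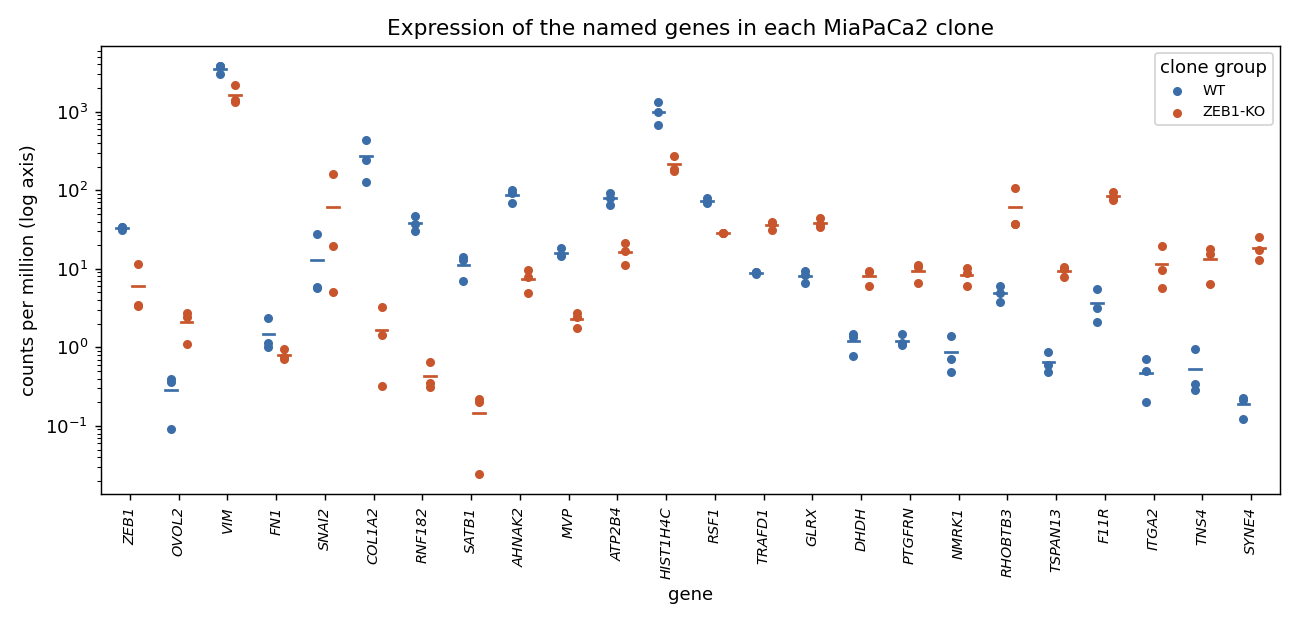
CPM on a log axis for the 24 named genes that were tested, with 1 point per clone and a short line at the mean of each group (WT in blue, ZEB1-KO in orange, n = 3 each). ZEB1 and the preset genes stand at the left, followed by genes past an adjusted p of 0.05 ordered by log2 fold change, from COL1A2 at -7.40 to SYNE4 at 6.54.

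Genes of epithelial junctions and polarity lay mostly higher in ZEB1-KO clones. Of 19 tested members, 17 had a positive log2 fold change, with a median of 1.23. F11R alone rose at an adjusted p below 0.05 over all genes, while 11 members rose when adjusted over the list alone and DESeq2 called 10 higher. Among those 11, the desmosome genes JUP, DSG2 and DSP had log2 fold changes of 2.78, 2.77 and 1.62, and the polarity genes INADL and LLGL2 had log2 fold changes of 2.00 and 1.93. The tight-junction genes CLDN4, MARVELD2 and OCLN followed with log2 fold changes of 1.61, 1.19 and 0.99. The list as a whole ranked above other genes by camera (adjusted p = 2.8e-14), with an adjusted p = 0.0907 with an estimated correlation, and the unadjusted camera p was also below 0.05 in 7 of the 9 other splits of the libraries into 3 and 3. CDH1, the gene for E-cadherin, had 2, 1 and 2 counts in the WT libraries and 1, 4 and 0 counts in the ZEB1-KO libraries, at or close to the floor, so that no difference was detectable at this depth. EPCAM was likewise at 0 counts in every library except ZEB1-KO replicate 2, which had 2 counts.

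The remaining epithelial lists had smaller medians. Of 15 tested genes of epithelial surface and trafficking, 10 had a positive log2 fold change. In the quasi-likelihood test 0 passed 0.05 over all genes, against 4 at an unadjusted p below 0.05. DESeq2 called 4 of the tested members higher. It also called S100A14 (18, 5 and 94 counts in ZEB1-KO replicates 1, 2 and 3) and EPS8L1 (11, 5 and 65 counts), too low in most libraries for the quasi-likelihood test. When adjusted over the list alone, 4 members rose. These were SPINT2, a protease inhibitor of the cell surface (15.2 CPM ± 8.25 in WT and 119 CPM ± 28.8 in ZEB1-KO clones, SD, n = 3 each), CDS1, BSPRY and PRRG4. The camera test gave an adjusted p of 0.00543, and an adjusted p of 0.185 with an estimated correlation. That estimate was -0.0214, below the preset 0.01, so that the higher p does not reflect a stronger correlation among these genes. The count of 0 became 1 without WT replicate 2 or ZEB1-KO replicate 2. Of 9 tested keratins, 7 had a positive log2 fold change, and KRT8 and KRT86 rose when adjusted over the list alone, by 1.25 and 2.03 on the log2 scale, where KRT86 shares near-identical sequence with KRT81. The keratin list had a camera adjusted p of 0.0662, which went to 0.0137 without ZEB1-KO replicate 1 and to 0.0485 without ZEB1-KO replicate 2, with an adjusted p of 0.714 with an estimated correlation. Transcription factors and splicing regulators of epithelial cells split evenly, with 5 of 10 tested members above 0 and a camera adjusted p of 0.982, and their median of 0.12 was -0.04 with limma-voom. Adjusted over the list alone, OVOL2, a repressor of mesenchymal genes, rose by 2.89 and KLF4 fell by 1.70 on the log2 scale. GRHL2 had 0 counts in all libraries. ESRP1, a regulator of epithelial splicing, had 3, 5 and 0 counts in the WT libraries and 12, 208 and 3 counts in the ZEB1-KO libraries. It was too low to enter the quasi-likelihood test, and DESeq2 called it higher (log2 fold change 4.68, adjusted p = 0.00415). Over the 4 epithelial lists together, 53 of 99 members were tested and 39 of these had a positive log2 fold change. The authors' deposited table called 11 of its 44 listed members higher and 1 lower.

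Mesenchymal and extracellular matrix genes lay mostly lower in ZEB1-KO clones. Of 18 tested members, 14 had a negative log2 fold change, with a median of -0.43. COL1A2 fell at an adjusted p below 0.05 over all genes, and 3 members fell when adjusted over the list alone, namely COL1A2, VIM and CALD1. The other tested collagen genes of the list were not called and had mixed signs. Their log2 fold changes were -2.21 (COL6A3), -0.35 (COL5A2), -0.14 (COL6A2), 0.13 (COL6A1) and 1.12 (COL3A1). COL1A1, the other type I collagen gene, had 1, 0 and 0 counts in the WT libraries and 4, 6 and 8 counts in the ZEB1-KO libraries. VIM, which encodes the intermediate filament vimentin, went from 3536 CPM ± 427 to 1635 CPM ± 467 (SD, n = 3 each), a log2 fold change of -1.11 with an SE of 0.25 and an adjusted p of 0.105 over all genes. VIM lies on the arm of chromosome 10 that carries ZEB1, whose genes on the same side of ZEB1 had a median log2 fold change of -0.36, with a median of 0.42 above other chromosomes in WT replicate 1 relative to the other WT clones. CALD1, the actin-binding caldesmon gene, had a log2 fold change of -1.08. FN1, the fibronectin gene, was at 1.49 CPM ± 0.739 in WT and 0.809 CPM ± 0.134 in ZEB1-KO clones (SD, n = 3 each; adjusted p = 0.336). CDH2, the N-cadherin gene, had 1, 0 and 0 counts in the WT libraries and 3, 11 and 69 counts in the ZEB1-KO libraries. It was too low for the quasi-likelihood test, and DESeq2 called it higher (log2 fold change 6.32, adjusted p = 0.00405), against the direction of most of the list, beside 4 members called lower. The camera test of the list gave an adjusted p of 0.00200, and an adjusted p of 0.333 with an estimated correlation, and the unadjusted p was below 0.05 in 5 of the 9 other splits. The camera adjusted p of the list was 0.0893 without ZEB1-KO replicate 3. The COL1A2 call was lost without WT replicate 2 (adjusted p = 0.0568), WT replicate 3 (0.129), ZEB1-KO replicate 1 (0.0589) or ZEB1-KO replicate 3 (0.0781), with log2 fold changes between -8.29 and -6.86.

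Other transcription factors of the epithelial-mesenchymal transition had 2 of 8 tested members above 0 and a camera adjusted p of 0.518. SNAI1, a repressor of E-cadherin, rose when adjusted over the list alone, by 2.06 on the log2 scale with an SE of 0.48, and no member passed 0.05 over all genes in the quasi-likelihood test, with 4 at an unadjusted p below 0.05 and 1 by DESeq2. SNAI2 had a log2 fold change of 2.23 that did not pass the test (adjusted p = 0.343) and rested on ZEB1-KO replicate 2, with 6479 counts. Without that library its log2 fold change was -0.075. ZEB2, the paralog of ZEB1, had at most 3 counts in any library.

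Stress response genes lay mostly higher in ZEB1-KO clones. Of 24 tested members, 19 had a positive log2 fold change, with a median of 0.67. None passed 0.05 over all genes in the quasi-likelihood test, with 13 at an unadjusted p below 0.05, whereas DESeq2 called 9 higher and 1 lower, and 11 rose and 1 fell when adjusted over the list alone. Those that rose included the immediate early genes FOSB, IER3 and FOS, with log2 fold changes of 2.97, 2.52 and 2.20, and ATF3, CHAC1 and ATF4 of the amino acid and unfolded protein response, with 2.48, 1.70 and 0.99. JUN was the member that fell, by 2.06 on the log2 scale, from 11.9 CPM ± 6.04 to 2.85 CPM ± 0.602 (SD, n = 3 each). The camera adjusted p was 9.2e-06, and the adjusted p was 0.163 with an estimated correlation. Of 19 tested TGF-beta response genes, 12 were above 0, with 6 at an unadjusted p below 0.05, 3 called higher by DESeq2 and 0 past 0.05 over all genes, and 3 rose when adjusted over the list alone, among them JUNB and SKIL with log2 fold changes of 1.98 and 1.22. Their camera adjusted p of 0.0261 became 0.714 with an estimated correlation. It rose above 0.05 without WT replicate 1 (0.123), WT replicate 3 (0.0502) or ZEB1-KO replicate 2 (0.303), or with the replicate number as a block (0.0743).

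Cell cycle and metabolic lists had smaller medians. Of 30 cell cycle genes, 23 were above 0 with a median log2 fold change of 0.32, and PLK1, a mitotic kinase, rose when adjusted over the list alone, from 26.4 CPM ± 7.51 to 105 CPM ± 47.1 (SD, n = 3 each). The camera adjusted p of 0.00572 became an adjusted p of 0.714 with an estimated correlation, and it was 0.0968 without WT replicate 2 and 0.229 without ZEB1-KO replicate 3. Of 20 hypoxia and glycolysis genes, DDIT4 rose when adjusted over the list alone, by 1.36 on the log2 scale. The camera adjusted p was 0.0662, against 0.0349 without WT replicate 3 and an adjusted p of 0.345 with an estimated correlation. The estimate for this list was -0.0267, again below the preset 0.01. Cholesterol synthesis (20 tested, median log2 fold change -0.14 and mean -0.05, with the direction up by camera, and a median of 0.01 with scaling by library size alone) and p53 targets (18 tested, median 0.04, and -0.0035 with limma-voom) had camera adjusted p-values of 0.982 each, with no member past 0.05 over all genes or adjusted over the list alone. The same held for YAP and TEAD targets, with 11 of 18 tested members below 0 and a camera adjusted p of 0.206. Their median of -0.14 was 0.01 with scaling by library size alone. Interferon response genes likewise had no such member, with 16 of 21 above 0, a larger median of 0.58 and a camera adjusted p of 0.0557. DESeq2 called 1 cell cycle, 1 hypoxia, 1 cholesterol, 1 p53 and 5 interferon genes higher, and 3 YAP and TEAD targets lower. At an unadjusted quasi-likelihood p below 0.05 these lists had 6, 6, 2, 2, 4 and 3 members. Among the 5 interferon genes, IFI27 and OASL were too low in most libraries for the quasi-likelihood test. IFI27 had 3, 187 and 15 counts and OASL 1, 671 and 54 counts in ZEB1-KO replicates 1, 2 and 3, so that both rested mainly on replicate 2. EBP, a sterol isomerase gene with a log2 fold change of 1.10 (adjusted p = 0.134), lies in a stretch of the X chromosome whose genes had a median log2 fold change of 0.90. The interferon p changed with the setting: it was 0.0373 with the replicate number as a block, 6.1e-05 without WT replicate 1, 0.0210 without WT replicate 3 and 1.2e-05 without ZEB1-KO replicate 1, and 0.714 with an estimated correlation.

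Lists that describe other cell types or gene families complete the comparison. Of the blood, endothelial and fibroblast markers, 6 were tested and split evenly about 0, with a camera adjusted p of 0.982. Of the pancreatic acinar and islet markers only 2 were high enough to test, so that no list test was made. Neuroendocrine and neuronal genes had 6 of 8 tested members below 0 and a camera adjusted p of 0.518. Protocadherins (11 tested, 6 above 0) had a camera adjusted p of 0.518, with 0.0216 without WT replicate 2, and HOX genes (15 tested, 9 above 0) one of 0.341, with 0.000439 without ZEB1-KO replicate 1, and with an estimated correlation the adjusted p was 0.790 and 0.831. The list of cancer-testis genes had 3 tested members, all below 0, with a camera adjusted p of 0.425, although its naming rule also took SSX2IP, a centrosomal gene of another kind. No member of these 6 lists passed 0.05 over all genes or adjusted over the list alone in the quasi-likelihood test. At an unadjusted p below 0.05 there were 3 HOX genes, of which DESeq2 called 1 higher, and 1 neuroendocrine gene.

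Ribosomal protein genes and histone genes, for which reads may also match other similar sequences, had negative medians. The histone values cover only RNA that the oligo(dT) primer copied, and need not follow the level of all histone RNA. Of 75 tested ribosomal protein genes, 53 were below 0, with a median log2 fold change of -0.15 and 0 members past 0.05, against 8 at an unadjusted p below 0.05 and 1 called lower by DESeq2, and the camera adjusted p of 0.0208 became 0.714 with an estimated correlation. It was 0.123 without WT replicate 1, 0.0558 without WT replicate 2, 0.303 without ZEB1-KO replicate 2 and 0.229 without ZEB1-KO replicate 3. Of 49 tested histone genes, 43 were below 0, with a median of -0.53, and HIST1H4C was the member that fell, a call kept without WT replicate 1 and lost without any other library (adjusted p up to 0.153). The histone camera adjusted p of 0.00488 became an adjusted p of 0.714 with an estimated correlation, and it was 0.837 without WT replicate 3 and 0.107 without ZEB1-KO replicate 2. Scaling by library size alone moved the median of all genes to 0.14 and that of the ribosomal protein genes to -0.01.

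**Figure D2:**
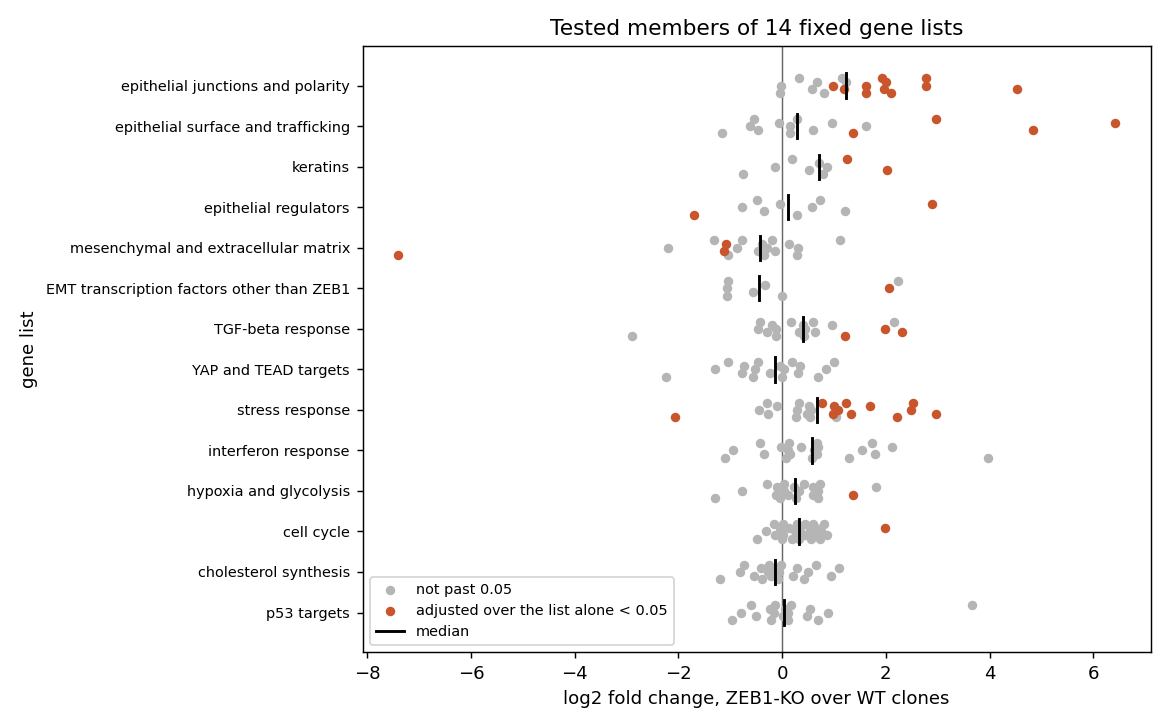
Log2 fold changes of ZEB1-KO over WT clones for the tested members of 14 gene lists, with 1 point per gene, orange where the edgeR quasi-likelihood p adjusted over the list alone was below 0.05, and a black bar at the median. Junction and polarity genes lie mostly to the right of 0, with a median of 1.23, and mesenchymal genes mostly to the left, with a median of -0.43 and COL1A2 at -7.40.

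The authors' deposited table, over fewer genes, called 311 genes higher and 212 lower at an adjusted p below 0.05 with edgeR's likelihood ratio test. The quasi-likelihood test, on the same counts, called 20 of these genes, namely every quasi-likelihood call that the authors' deposited table listed. Calls of the authors' deposited table included F11R at a log2 fold change of 4.52, DSG2 at 2.76 and SPINT2 at 2.96. They also included KRT8 at 1.24, VIM at -1.12 and COL1A2 at -7.36. Of these, the quasi-likelihood test called only F11R and COL1A2. The clones themselves varied: the biological coefficient of variation was 0.360 among WT and 0.382 among ZEB1-KO clones, and correlations of log2 CPM lay between 0.948 and 0.966 for pairs of clones within a group and between 0.927 and 0.951 across groups. The first principal component held 37.7% of the variance, with WT clones at -57.6 to -20.9 and ZEB1-KO clones at 17.1 to 57.9. For 23.6% of the genes tested, the 3 values of one group lay entirely above those of the other, against a chance share of 10%. That 10% is an average over all splits of the libraries. Genes are not independent of each other and the share was not computed for other splits, so its spread by chance is unknown.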

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

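The likelihood ratio test, robust estimation and the adjusted p below 0.1 were chosen only after the results were seen. All 24 calls kept their sign under every edgeR, limma-voom and DESeq2 alternative that tested them, and RNF182, SYNE4, F11R and AHNAK2 stayed past 0.05 under all 20 alternatives. For the 24 named genes with a test, 376 of 478 alternative values kept their direction and side of the threshold, 89 lost the call, 12 gained one and 1 turned: SNAI2, at -0.075 without ZEB1-KO replicate 2 and up to 3.43 without another library. Genes higher and lower numbered 87 and 47 without a filter, 570 and 365 with DESeq2 (over its own set of genes), 343 and 223 with the exact test, 376 and 241 with the likelihood ratio test, 34 and 22 with robust estimation, and 149 and 96 at an adjusted p below 0.1. On log2 TPM with limma they were 82 and 19 (plus 1), 76 and 18 (plus 0.1) and 63 and 17 (no filter). Leaving out 1 library gave 3 to 16 higher and 2 to 10 lower. A replicate block gave 11 and 9, with 9 of the 24 calls shared. Epithelial members called higher were 4 with library size alone, 10 without a filter, 19 with DESeq2, 12 with the exact test, 3 with limma-voom, 8 with each of the TPM settings (8 plus 1, 8 plus 0.1, 8 no filter), 2 with the block, 13 with the likelihood ratio test, 6 with robust estimation and 1 to 2 without 1 library. Mesenchymal members called lower were 4 with DESeq2, 3 with the exact test, 3 with the likelihood ratio test, 0 with the block, 0 with robust estimation and 0 to 1 without 1 library. ZEB1 passed 0.05 at a log2 fold change of -2.43 without a filter, -2.41 with DESeq2, -2.43 with the exact test, -1.76 on log2 TPM plus 1 and -2.43 with the likelihood ratio test, and lay between -3.27 and -2.14 without 1 library. With an estimated correlation the adjusted p was 0.0907 for the junction list and 0.333 for the mesenchymal list, which had 0.0898 with fry and 4.2e-05 to 0.0893 without 1 library. Tested by fry against no change, rather than against other genes, the junction (0.0128), surface (0.0406), stress (0.0262) and hypoxia (0.0406) lists had an adjusted p below 0.05, while camera with an estimated correlation gave 0.185, 0.163 and 0.345 for the last 3. The cause of these differences was not tested. On simulated data the likelihood ratio test and DESeq2 made 23.2% and 25.7% false calls, against 9.83% for the quasi-likelihood test, each above the 0.05 threshold. The simulations gave a mean of 103.8 quasi-likelihood, 155.4 likelihood ratio and 164.4 DESeq2 calls, against 24, 617 and 935 on the data. These rates thus cannot tell which share of the calls on the data is false. CDH1, EPCAM, ESRP1, GRHL2, CDH2 and ZEB2 did not pass the count filter of the quasi-likelihood test.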

Other observations

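The tests along chromosomes and the number of other splits with a camera p below 0.05 were chosen only after the result was seen, and the genes of the next paragraph after their values were seen, while the counts over splits of the libraries were planned, although 2 of them use the likelihood ratio test, itself chosen after the data were seen.

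Further genes stood among the smallest p-values of the authors' deposited table. They were picked outside the lists, the named genes and the calls of edgeR's quasi-likelihood test. That none passed 0.05 in that test thus follows from how they were picked. LY6E, an interferon-inducible surface protein gene, was at 24.3 CPM ± 4.98 in WT and 165 CPM ± 92.7 in ZEB1-KO clones (SD, n = 3 each). The nucleoside transporter gene SLC29A1 was at 34.1 CPM ± 3.65 and 129 CPM ± 48.7 (SD, n = 3 each). CD274, which encodes the immune checkpoint ligand PD-L1, had 29, 5 and 31 counts in WT and 293, 186 and 791 counts in ZEB1-KO libraries, a log2 fold change of 4.42 with an adjusted p of 0.0885. Among genes with lower values, UBE2E3, a ubiquitin-conjugating enzyme gene, was at 463 CPM ± 115 in WT and 109 CPM ± 35.6 in ZEB1-KO clones (SD, n = 3 each). CDKN2C, a cell cycle inhibitor gene, was at 29.2 CPM ± 19.6 and 3.76 CPM ± 1.31 (SD, n = 3 each). BHLHE41, a transcriptional repressor gene of the circadian clock, had 296, 227 and 60 counts in WT and 3, 0 and 12 counts in ZEB1-KO libraries.

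The 6 libraries can be divided into 3 and 3 in 10 ways, so that the share of splits with a result as large is never under 0.1, and for each of 5 results only 1 split, the real one, was as large. The quasi-likelihood test gave 24 calls, with 1 in the highest other split, and the likelihood ratio test 617, with 77. Each other split has clones of both groups on either side, which raises the spread within sides if the groups differ. Fewer calls there are thus partly built in, and a chance division of the clones is not excluded. Epithelial members called in one direction by the likelihood ratio test numbered 13, with 1 in the highest other split. The unadjusted camera p was 1.3e-15 for the junction list, with 2.6e-06 as the smallest of the other splits, and 0.000286 for the mesenchymal list, with 0.00140. It was below 0.05 in 7 of the 9 other splits for the junction list and in 5 of 9 for the mesenchymal list.

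On chromosome 10, 75 ordered genes, from ZMYND11 to MTPAP, lie between the end of the short arm and ZEB1 in the order of GRCh38. Their median log2 fold change was -0.36, and that of the 296 genes past ZEB1 was 0.04. Shifts of this size also stood elsewhere. In 872 windows of 20 ordered genes, the largest shift on chromosome 10 ranked 14, at -0.49. Windows on chromosomes X, 11, 6, 12, 21, 16, 3 and 19 ranked above it. The median of all ordered genes of chromosome 21 was -0.33. After removal of the trend with GC content and gene length the segment's median was -0.39, which argues against that trend as the whole cause. The middle 95% of equally long runs on other chromosomes lay at -0.26 to 0.24, and 20 of 7067 runs were as low. The genes of this segment were chosen after the data were seen, which the band does not allow for. Relative to the WT mean, 86.7%, 52% and 92% of these genes lay below the rest of the chromosome in ZEB1-KO replicates 1, 2 and 3, but that rest was itself not level: against other chromosomes its median was 0.19, -0.25 and 0.21 there, and in WT replicate 1, relative to the other WT clones, it was 0.51 with the segment at 0.42. Fewer copies of the segment in a ZEB1-KO clone or more copies elsewhere on chromosome 10 in ZEB1-KO replicates 1 and 3 are candidate explanations. More copies of chromosome 10 in WT replicate 1 are another. All stay open, since DNA was not measured. Leaving WT replicate 1 out of the reference moved the segment from -0.41, -0.33 and -0.50 to -0.27, -0.20 and -0.34 against other chromosomes in ZEB1-KO replicates 1, 2 and 3, with 69.3%, 62.7% and 70.7% of its genes below them, against 66.7% in WT replicate 2 relative to WT replicate 3, and the rest of chromosome 10 then lay at 0.36, -0.09 and 0.37.

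On the X chromosome, the 40 ordered genes from RBM10 to HSD17B10 had a median log2 fold change of 0.90. After removal of the trend with GC content and gene length it was 0.77, outside the middle 95% of equally long runs (-0.30 to 0.25). That band does not allow for the choice of the segment after its values were seen. WT clones themselves differed by 1.26 on the log2 scale in the median of these genes, which argues against loss of ZEB1 as the whole cause. Relative to WT replicate 2, 95% of the genes lay below the rest of the chromosome in WT replicate 1 and 95% in WT replicate 3, but the segment and this reference were picked for showing the pattern, so that these shares restate it. A difference in DNA copies of the segment among the WT clones may account for it, and stays open. The authors' deposited table called 8 of the 39 listed genes of this segment higher, EBP and PLP2 among them.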
